A study of Mus musculus with 6 samples.

How the data were processed

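Naive CD4+ T cells from mouse spleen (strain C57BL/6, age 3 weeks in the labels) were activated for 3 days with antibodies to CD3 and CD28 under conditions that favour T helper 1 (Th1) cells, with a vehicle or with 20 µM LPC. The labels do not spell out LPC and do not name the vehicle. The 6 libraries form 2 groups of 3, assigned from the agent given in the labels. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

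Total RNA was sequenced on a BGISEQ-500, per the labels' protocols. Reads were aligned to GRCm38 with Bowtie2, and gene expression was given as FPKM (fragments scaled for exon length and for the number of mapped reads) by RSEM, per the labels' protocols. Versions and settings of these tools are not given in the sources used here. The deposited values are FPKM rounded to the nearest hundredth, 1 file per library, for the same 18046 genes. These are protein-coding genes only, and no mitochondrial gene was listed. RSEM divides reads that match several genes by estimate, so values of near-identical copies are less certain. Examples among the genes named or counted in lists are the Oas and Gzm families, Serpinb6b, Ccl3, Eno1 and Gapdh. FPKM is relative to each library's own total, so a rise of abundant genes lowers the listed value of others.

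Gene symbols that had been turned into dates (24) were restored through the gene identifier. Of the identifiers, 17914 (99.3%) matched the RefSeq gene table of GRCm38.p6, which gave the coordinates. The FPKM sums were 575091, 556561 and 588274 in vehicle replicates 1 to 3 and 583242, 562046 and 641026 in LPC replicates 1 to 3. Read totals are not part of the files. The values from 0.03 to 0.3 FPKM of genes with 1 listed transcript came nearest to whole reads at 18.50 M reads in vehicle replicate 2 and at 18.75 M in the other libraries. The mean distance to a whole read was 0.156 to 0.178, against at least 0.208 after gene lengths were shuffled, so this depth is an estimate. No count test was used, since the values are not counts.

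The comparison used limma 3.58.1 in R 4.3.3 (limma-trend, group as the single term) on log2(FPKM + 1) of the 10138 genes with FPKM of 1 or more in 3 or more libraries, with Benjamini-Hochberg adjustment. All log2 changes are on this scale, LPC minus vehicle, and understate the change of genes with low values. A gene was called changed at an adjusted p under 0.05, and a further count added the rule in the labels' protocols of a change over 2-fold. Gene lists with 5 or more tested members (31 of 39) were tested with camera (limma, preset correlation 0.01), which compares a list with all other tested genes, with Benjamini-Hochberg adjustment over the lists. The lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined. The rule named the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, with a mean FPKM of 5 or more in the higher group and a symbol other than a clone name. It also named a set of helper T cell genes and markers whatever their result, and up to 4 changed members of each list that shifted or had 3 or more changed members.

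The test was tested on simulated values made from the means and spread of the 10138 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold between LPC and vehicle. It recovered 64% of the former and 87% of the latter, with 5 false calls among 156. The simulated noise was independent between genes and held no trend with GC share or length. The share of false calls among the real calls can therefore differ. The comparison was repeated with quantile normalization, median centring, no filter on low values, a mean FPKM of 5 or more, a pseudocount of 0.1, the replicate number as a block, leaving out each library in turn and, for lists, an estimated correlation and fry. Removal of each library's trend with the GC share and length of transcripts (natural splines with 4 degrees of freedom, 98.7% of tested genes) was added after seeing the data.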

Results

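RNA sequencing measured gene expression in naive CD4+ T cells of mouse spleen after 3 days of activation under Th1-polarizing conditions with vehicle (n = 3) or 20 µM LPC (n = 3). The comparison asked how LPC altered gene expression during Th1 differentiation. Each library listed 18046 genes, of which 10002 to 10139 had an FPKM of 1 or more. The estimated depth was 18.50 to 18.75 M reads per library. On the first principal component, which held 58.4% of the variance, LPC libraries lay at 10.84, 3.03 and 21.10 and vehicle libraries at -10.76, -15.76 and -8.43. LPC replicate 3 also had the highest FPKM sum (641026) and the lowest share of genes at 0 (17.9%, against 19.4% to 20.2%), and its 1001 genes with the longest transcripts had a median deviation of -0.24 on the log2 scale. Across genes the log2 change correlated with GC share (r = 0.25) and with log2 length (r = -0.22).

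The metallothionein genes Mt2 and Mt1, which encode small metal-binding proteins, rose most with LPC. Mt2 rose from 8.15 ± 1.38 to 70.9 ± 11.2 FPKM (SD, n = 3 each; log2 change 2.97, SE 0.13, limma adjusted p = 1.7e-08). Mt1 rose from 11.9 ± 0.484 to 67.0 ± 10.4 FPKM (2.38, SE 0.11, adjusted p = 2.4e-08), and Mt3 rose from 2.34 ± 0.515 to 7.89 ± 2.36 FPKM. These 3 genes lie on chromosome 8 of GRCm38, Mt3 at 94152607 to 94154148, Mt2 at 94172618 to 94173567 and Mt1 at 94178883 to 94180327. The calcium-binding protein gene S100a6 rose by a log2 change of 1.90 and Il10, which encodes an anti-inflammatory cytokine, by 1.58. Ly6g, a surface antigen gene best known from neutrophils, rose from 3.77 ± 0.883 to 12.7 ± 4.03 FPKM. Further large rises by the naming rule were Nkain1 (1.24), the protease inhibitor gene Serpine2 (1.16), the lipid droplet coat gene Plin2 (1.10), Upp1 (1.08), Gatm (1.04) and Tnfrsf8, which encodes CD30 (1.02). Falls were smaller. The actin-bundling gene Fscn1 fell from 36.5 ± 1.05 to 15.7 ± 0.917 FPKM (log2 change -1.17, SE 0.09, adjusted p = 8.9e-06). Nsg2 fell from 12.9 ± 1.23 to 5.94 ± 0.639 FPKM. Pou6f1 and Phyhd1 each had a log2 change of -1.05, the nuclear receptor gene Nr4a3 of -0.95, Fam171b of -0.92, Pacsin1 of -0.88 and Plagl1 of -0.85. Trat1, an adaptor of the T cell receptor complex, had a log2 change of -0.83, and St6gal1, the histone demethylase gene Kdm6b and Hes7 each had -0.81.

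**Figure D1:**
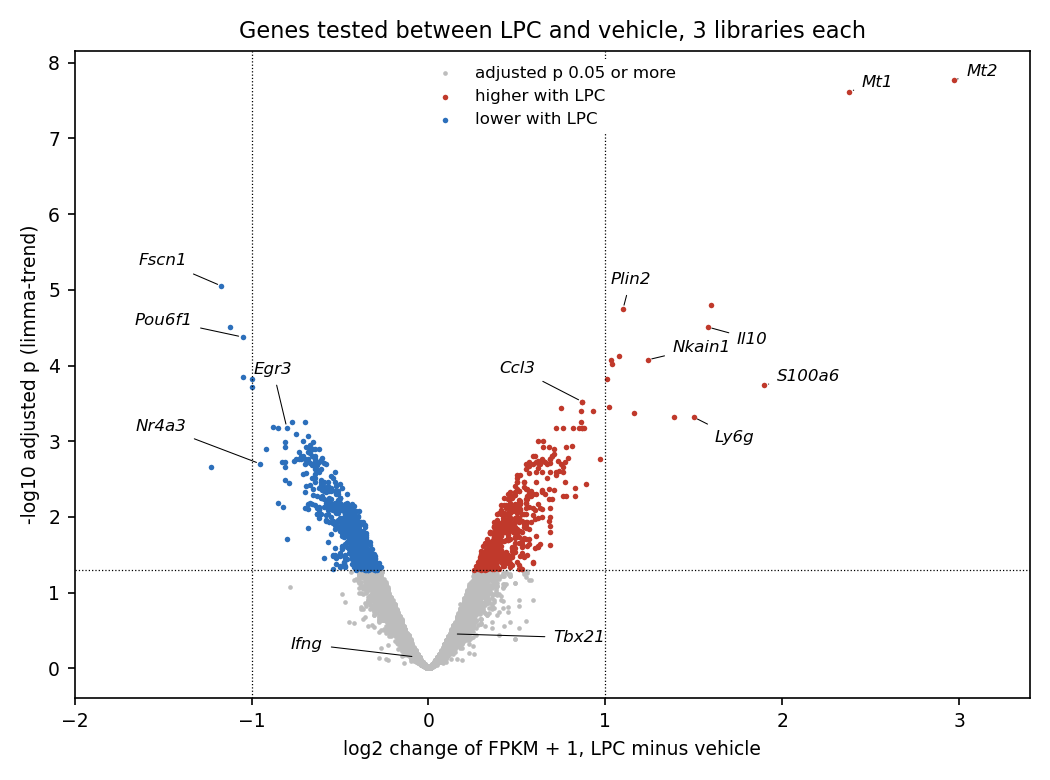
Each point is 1 of the 10138 genes tested, with the log2 change of FPKM + 1 (LPC minus vehicle) on the x axis and -log10 of the limma adjusted p on the y axis; dotted lines mark a 2-fold change and an adjusted p of 0.05. Mt2 and Mt1 lie apart from all other genes at log2 changes of 2.97 and 2.38, and Ifng and Tbx21 lie among the genes that did not pass.

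Across the 10138 genes tested, 1392 changed at an adjusted p under 0.05, 590 higher and 802 lower with LPC. Most changes were small, with a median absolute log2 change of 0.42, and 72.9% lay under 0.5. Over 2-fold, 15 genes rose and 5 fell, 20 in all, against 57 with a pseudocount of 0.1. LPC and vehicle libraries did not overlap for 34.5% of tested genes, where chance gives 10%. The number of calls depended on single libraries, falling to 513 without vehicle replicate 1, 566 without vehicle replicate 2 and 702 without LPC replicate 1, and to 464 with no filter on low values. A fit without 1 library also has less power, so a lost call is not by itself a smaller change. The share of calls that were higher with LPC was 42.4%, and 53.1% after median centring.

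Ifng and Tbx21 did not pass the test. Ifng, which encodes interferon-gamma, was listed at 1223 ± 89.1 FPKM with vehicle and 1165 ± 43.9 with LPC (n = 3 each; log2 change -0.07, 95% interval -0.30 to 0.16, limma adjusted p = 0.706). Tbx21, which encodes the Th1 transcription factor T-bet, was listed at 101 ± 8.60 and 111 ± 7.41 FPKM (0.14, interval -0.07 to 0.34, adjusted p = 0.35). Ifng lies on chromosome 10 at 118441046 to 118445894 and Tbx21 on chromosome 11 at 97098007 to 97115331. The log2 changes of Il12rb2 (0.14), Cxcr3 (0.17) and Tnf (-0.05) did not pass either. Of 25 tested Th1 lineage genes 3 rose, 4 fell and 18 did not pass, with 5 rising and 5 falling when adjusted over the list alone. The chemokine gene Ccl3 rose from 47.7 ± 3.02 to 88.2 ± 10.7 FPKM, and the transcription factor gene Hlx and the inhibitory receptor gene Havcr2 rose by log2 changes of 0.72 and 0.38. Fasl, a death receptor ligand gene, had a log2 change of -0.62, the cytokine gene Lta of -0.45, Eomes of -0.49 and Stat4, a mediator of interleukin-12 signals, of -0.35. The list as a whole did not shift (camera adjusted p = 0.405). Rises in the Th1 lineage list numbered 5 without LPC replicate 2, and falls in the Th1 lineage list numbered 2 without vehicle replicate 2 or 3 or LPC replicate 1. Stat4 did not pass without vehicle replicate 1 (adjusted p = 0.054), vehicle replicate 2 (0.132), vehicle replicate 3 (0.0868), LPC replicate 1 (0.0786) or LPC replicate 3 (0.0558). Its log2 change in those fits was -0.41 to -0.29. Eomes did not pass without vehicle replicate 2 (adjusted p = 0.055), vehicle replicate 3 (0.0539) or LPC replicate 1 (0.0566). Havcr2 did not pass without vehicle replicate 1 (adjusted p = 0.114), vehicle replicate 3 (0.0655) or LPC replicate 1 (0.0961).

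**Figure D2:**
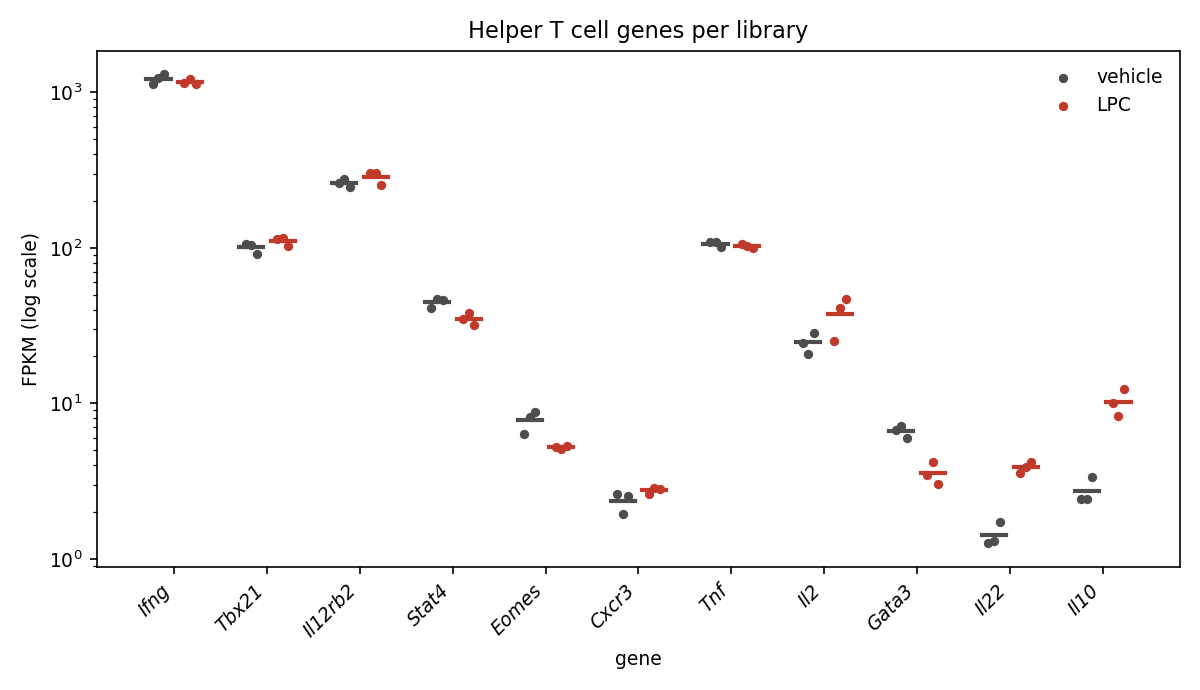
FPKM (log axis) of 11 helper T cell genes in each library, vehicle in grey and LPC in red; points are single libraries and bars are group means of 3. Ifng and Tbx21 overlap between groups, Gata3 lies lower with LPC (3.54 against 6.60 FPKM) and Il10 higher (10.2 against 2.74 FPKM).

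Genes of other helper lineages moved in both directions. Gata3, the Th2 transcription factor gene, fell from 6.60 ± 0.616 to 3.54 ± 0.586 FPKM (n = 3 each; log2 change -0.75, limma adjusted p = 0.00171), and the chemokine receptor gene Ccr8 had a log2 change of -0.68. Those were the 2 changed genes among 10 tested Th2 genes, also when adjusted over the list alone (camera adjusted p = 0.621). Of 7 tested Th17 genes 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0835). Il22 rose from 1.43 ± 0.252 to 3.89 ± 0.325 FPKM and Il6st had a log2 change of -0.50. Among 12 regulatory T cell genes Il10 and Tigit rose and Nrp1 fell, as they did when adjusted over the list alone; the list median was -0.11 and its mean 0.05, with the test up at a camera adjusted p of 0.867. Il6st did not pass without vehicle replicate 1 (adjusted p = 0.0533), vehicle replicate 2 (0.106), LPC replicate 1 (0.071) or LPC replicate 3 (0.0633). Nrp1 did not pass without vehicle replicate 1 (adjusted p = 0.0569), vehicle replicate 3 (0.0762), LPC replicate 1 (0.0831) or LPC replicate 3 (0.0606). Il4, Il17a and Foxp3 stayed under the filter, with at most 0.36, 0.58 and 0.49 FPKM in any library.

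Of 10 tested follicular helper genes 5 fell and none rose (7 fell when adjusted over the list alone; camera adjusted p = 0.00424; adjusted p = 0.488 with an estimated correlation). The homing receptor gene Cxcr5 fell from 4.98 ± 0.867 to 2.80 ± 0.303 FPKM, and Tcf7 had a log2 change of -0.45, while Bcl6 did not pass (-0.20, adjusted p = 0.235). Falls in the follicular helper list numbered 2 without vehicle replicate 2 or LPC replicate 1 and 3 without vehicle replicate 1. Of 20 naive and quiescence genes 4 fell and none rose, and 7 fell when adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.537 with an estimated correlation). Dapl1 had a log2 change of -0.68 and the interleukin-7 receptor gene Il7r of -0.42. Falls in the naive and quiescence list numbered 2 without vehicle replicate 2 and 7 without LPC replicate 2. Il7r did not pass without vehicle replicate 2 (adjusted p = 0.0704) or vehicle replicate 3 (0.0534). Among 9 inhibitory receptor genes 2 rose and 4 fell (2 and 5 when adjusted over the list alone; camera adjusted p = 0.435); Tox had a log2 change of -0.69 and Vsir of -0.43. Rises in the inhibitory receptor list numbered 1 without vehicle replicate 1 or 3 or LPC replicate 1, and falls in the inhibitory receptor list numbered 2 without vehicle replicate 2.

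Among 24 T cell activation genes 1 rose and 5 fell (2 and 6 when adjusted over the list alone; camera adjusted p = 0.328, and 0.0469 with quantile normalization). Nr4a1 fell from 292 ± 8.27 to 182 ± 23.7 FPKM (n = 3 each; log2 change -0.68, limma adjusted p = 0.00171), and Egr3, Jun and Fos had log2 changes of -0.80, -0.48 and -0.43. The transferrin receptor gene Tfrc rose by 0.43. Tfrc did not pass without vehicle replicate 1 (adjusted p = 0.0792). Jun did not pass without vehicle replicate 1 (adjusted p = 0.0637). Fos did not pass without vehicle replicate 1 (adjusted p = 0.0552), vehicle replicate 2 (0.07) or LPC replicate 1 (0.0607). Il2 was listed at 24.6 ± 3.80 and 37.6 ± 11.4 FPKM and did not pass (0.56, adjusted p = 0.0543), though it passed after removal of GC and length trends (0.0312), without vehicle replicate 3 (0.0264) and without LPC replicate 1 (0.00978). Cd69 did not pass (-0.02). Rises in the T cell activation list numbered 0 without vehicle replicate 1 and 2 without vehicle replicate 3 or LPC replicate 1, and falls in the T cell activation list numbered 3 without vehicle replicate 1. Among 15 IL-2 and STAT5 target genes 3 fell, among them Socs3 and Lta, and none rose (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.29). Rises in the IL-2 and STAT5 target list numbered 1 without LPC replicate 2. Among 10 cytotoxic effector genes 2 rose and 2 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.784, with a list median of -0.03 and a mean of -0.01 against a test direction of up). The granzyme gene Gzmc rose by a log2 change of 0.69. Rises in the cytotoxic effector list numbered 1 without vehicle replicate 1 or 2 or LPC replicate 1, and falls in the cytotoxic effector list numbered 1 without vehicle replicate 3.

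Of 23 sterol synthesis and uptake genes 5 rose and none fell (7 when adjusted over the list alone; camera adjusted p = 4.4e-05; adjusted p = 0.488 with an estimated correlation). Idi1 rose from 3.13 ± 0.304 to 5.05 ± 0.695 FPKM, and Lss rose by a log2 change of 0.39. Lss did not pass without vehicle replicate 1 (adjusted p = 0.0757), vehicle replicate 2 (0.132) or LPC replicate 1 (0.0925). Rises in the sterol synthesis and uptake list numbered 2 without vehicle replicate 1 or 2 or LPC replicate 1. Of 19 glycolysis genes 7 rose and none fell (8 when adjusted over the list alone; camera adjusted p = 5.7e-04; adjusted p = 0.52 with an estimated correlation). The lactate exporter gene Slc16a3 rose from 27.3 ± 1.21 to 46.8 ± 9.05 FPKM, and Pfkl rose by 0.64. Rises in the glycolysis list numbered 2 without vehicle replicate 1 or 2, 3 without LPC replicate 1 and 4 without vehicle replicate 3. Of 22 G1/S genes 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 5.5e-04; adjusted p = 0.539 with an estimated correlation), among them Chaf1b and the replication helicase gene Mcm2 (both 0.37). Rises in the G1/S list numbered 0 without vehicle replicate 3 or LPC replicate 1 and 1 without vehicle replicate 1 or 2. Of 22 G2/M genes 1 rose, Kif20a, also when adjusted over the list alone (camera adjusted p = 0.064). That list passed without vehicle replicate 2 (0.045), vehicle replicate 3 (0.0136) or LPC replicate 3 (0.0188), with median centring (0.0487) and after removal of GC and length trends (0.00424). Rises in the G2/M list numbered 0 without vehicle replicate 1, 2 without LPC replicate 2 and 3 without LPC replicate 3. Chaf1b did not pass without vehicle replicate 1 (adjusted p = 0.0785), vehicle replicate 3 (0.0805) or LPC replicate 1 (0.052). Mcm2 did not pass without vehicle replicate 2 (adjusted p = 0.064), vehicle replicate 3 (0.0887) or LPC replicate 1 (0.061). Kif20a did not pass without vehicle replicate 1 (adjusted p = 0.0555).

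Of 26 oxidative phosphorylation genes 2 rose, Cox7a2 (log2 change 0.60) and Ndufv1 (0.34), also when adjusted over the list alone (camera adjusted p = 7.1e-04; adjusted p = 0.625 with an estimated correlation). That shift was lost without LPC replicate 3 (adjusted p = 0.0614) and with quantile normalization (0.0588). Rises in the oxidative phosphorylation list numbered 0 without vehicle replicate 1 or 2 or LPC replicate 1 and 8 without LPC replicate 2. Cox7a2 did not pass without vehicle replicate 1 (adjusted p = 0.054), vehicle replicate 2 (0.0593) or LPC replicate 1 (0.0721), nor with median centring (0.0656). Ndufv1 did not pass without vehicle replicate 1 (adjusted p = 0.0582), vehicle replicate 2 (0.192), vehicle replicate 3 (0.0581) or LPC replicate 1 (0.099), nor with quantile normalization (0.0556). Of 17 fatty acid oxidation and PPAR target genes 3 rose and none fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0155; adjusted p = 0.488 with an estimated correlation). Plin2 rose from 12.2 ± 0.307 to 27.2 ± 1.80 FPKM, and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, rose by 0.40. Rises in the fatty acid oxidation and PPAR target list numbered 1 without vehicle replicate 1, and falls in the fatty acid oxidation and PPAR target list numbered 1 without LPC replicate 1. Cpt1a did not pass without vehicle replicate 1 (adjusted p = 0.0609), vehicle replicate 2 (0.0504) or vehicle replicate 3 (0.0551). Of 14 fatty acid synthesis and desaturation genes 1 rose and 2 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.789), with a list median of 0.07, a mean of -0.01 and the test up. Scd1 had a log2 change of -0.40 and Fasn of 0.37. Rises in the fatty acid synthesis list numbered 0 without vehicle replicate 1, 2 or 3 or LPC replicate 1 or 2 and 2 without LPC replicate 3, and falls in the fatty acid synthesis list numbered 0 without vehicle replicate 2 or 3 and 1 without vehicle replicate 1 or LPC replicate 1. Scd1 did not pass without vehicle replicate 2 (adjusted p = 0.0713) or vehicle replicate 3 (0.055). Fasn did not pass without vehicle replicate 1 (adjusted p = 0.0974), vehicle replicate 2 (0.101), vehicle replicate 3 (0.11), LPC replicate 1 (0.157) or LPC replicate 2 (0.072). Of 7 sterol efflux and LXR target genes Abcg1 and Mylip fell, also when adjusted over the list alone (camera adjusted p = 0.307). Mylip did not pass without vehicle replicate 1 (adjusted p = 0.0774) or LPC replicate 1 (0.0702).

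Genes that handle or sense lysolipids gave single changes without a shift of either list. Among 22 lysophospholipid and phosphatidylcholine genes 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.874). Enpp2, which encodes the secreted enzyme autotaxin, rose from 0.59 ± 0.0954 to 1.93 ± 0.409 FPKM, and Pemt rose by a log2 change of 0.54. Falls in the lysophospholipid and phosphatidylcholine list numbered 0 without vehicle replicate 1, 2 or 3 or LPC replicate 1. Among 11 lysolipid and proton-sensing receptor genes 1 rose and 4 fell (1 and 6 when adjusted over the list alone; camera adjusted p = 0.269). S1pr3 fell from 2.72 ± 0.296 to 1.39 ± 0.165 FPKM and S1pr4 rose from 17.1 ± 0.365 to 24.0 ± 2.51 FPKM. Falls in the lysolipid and proton-sensing receptor list numbered 1 without vehicle replicate 1 or 2 or LPC replicate 1 and 2 without LPC replicate 3. Gpr132 was listed at 65.8 ± 1.85 and 61.5 ± 5.12 FPKM and did not pass (-0.10, adjusted p = 0.477).

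Of 19 type I interferon response genes 7 fell and none rose (8 when adjusted over the list alone; camera adjusted p = 0.0153; adjusted p = 0.625 with an estimated correlation), a shift that was lost without LPC replicate 1 (adjusted p = 0.102). Rsad2 fell from 8.57 ± 0.199 to 4.69 ± 0.987 FPKM and Oasl1 had a log2 change of -0.45. Falls in the type I interferon list numbered 2 without vehicle replicate 1 or 2 or LPC replicate 1 and 4 without vehicle replicate 3 or LPC replicate 3. Of 25 interferon-gamma response genes 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.064), and the immunoproteasome gene Psmb10 rose by 0.51. This list passed without vehicle replicate 1 (0.0278), vehicle replicate 2 (0.0243), LPC replicate 1 (0.0301) or LPC replicate 3 (0.0481), and after removal of GC and length trends (0.0358). Rises in the interferon-gamma response list numbered 1 without vehicle replicate 1, 2 or 3, and falls in the interferon-gamma response list numbered 0 without vehicle replicate 1 or LPC replicate 1 and 3 without LPC replicate 2. Of 15 chemokine and inflammatory cytokine genes 4 rose and 1 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.0263; adjusted p = 0.488 with an estimated correlation). Ccl3, Ccl22 and Csf1 rose by 0.87, 0.69 and 0.64. The shift of this list was lost without LPC replicate 2 (adjusted p = 0.0834) or LPC replicate 3 (0.0614), with quantile normalization (0.0777), with a mean FPKM of 5 or more (0.291) and after removal of GC and length trends (0.118). Falls in the chemokine and cytokine list numbered 0 without vehicle replicate 1 or 2 or LPC replicate 1 and 2 without LPC replicate 3.

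Of 22 integrated stress response genes Psph and Stc2 rose (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0107; adjusted p = 0.537 with an estimated correlation), by 0.54 and 0.28. The shift was lost with quantile normalization (adjusted p = 0.189). Rises in the integrated stress response list numbered 1 without vehicle replicate 1, 2 or 3 or LPC replicate 1 and 4 without LPC replicate 3, and falls in the integrated stress response list numbered 1 without LPC replicate 3. Stc2 did not pass without vehicle replicate 1 (adjusted p = 0.146), vehicle replicate 2 (0.134), vehicle replicate 3 (0.138) or LPC replicate 1 (0.0845), nor with quantile normalization (0.0667). Of 17 p53 and apoptosis genes 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.269); Phlda3 and the cell cycle inhibitor gene Cdkn1a rose by 0.75 and 0.52. Falls in the p53 and apoptosis list numbered 0 without vehicle replicate 1 and 1 without vehicle replicate 2 or LPC replicate 1. Of the unfolded protein response (19 genes tested), NRF2 (13) and heat shock (10) lists 1 gene each changed, also when adjusted over each list alone, Derl3 and Hmox1 upward and Hspa4l downward (camera adjusted p = 0.11, 0.064 and 0.239). Derl3 did not pass without vehicle replicate 1 (adjusted p = 0.102), vehicle replicate 2 (0.0871), vehicle replicate 3 (0.0686), LPC replicate 1 (0.0703) or LPC replicate 3 (0.064). Hmox1 did not pass without vehicle replicate 1 (adjusted p = 0.0905), vehicle replicate 2 (0.0991), vehicle replicate 3 (0.117), LPC replicate 1 (0.0915) or LPC replicate 2 (0.0555). Hspa4l did not pass without vehicle replicate 2 (adjusted p = 0.0542) or LPC replicate 1 (0.0567). The NRF2 list passed without vehicle replicate 1 (0.0406), with no filter on low values (0.027) and after removal of GC and length trends (0.0358), which also let the unfolded protein response list pass (0.0275). Rises in the unfolded protein response list numbered 0 without vehicle replicate 1, 2 or 3 or LPC replicate 1 or 3 and 2 without LPC replicate 2. Of 15 hypoxia genes 2 rose (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.137). Rises in the hypoxia list numbered 0 without vehicle replicate 1 or 3 or LPC replicate 1 and 1 without vehicle replicate 2 or LPC replicate 2 or 3, and falls in the hypoxia list numbered 1 without LPC replicate 2. No gene passed limma among 23 ribosomal protein genes (camera adjusted p = 0.789; median 0.02, mean -0.01, test up) or 11 pan-T and CD4 marker genes (0.988; median 0.02, mean -0.03, test down), also when adjusted over each list alone. Cd4 was listed at 197 ± 10.2 and 164 ± 17.5 FPKM.

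**Figure D3:**
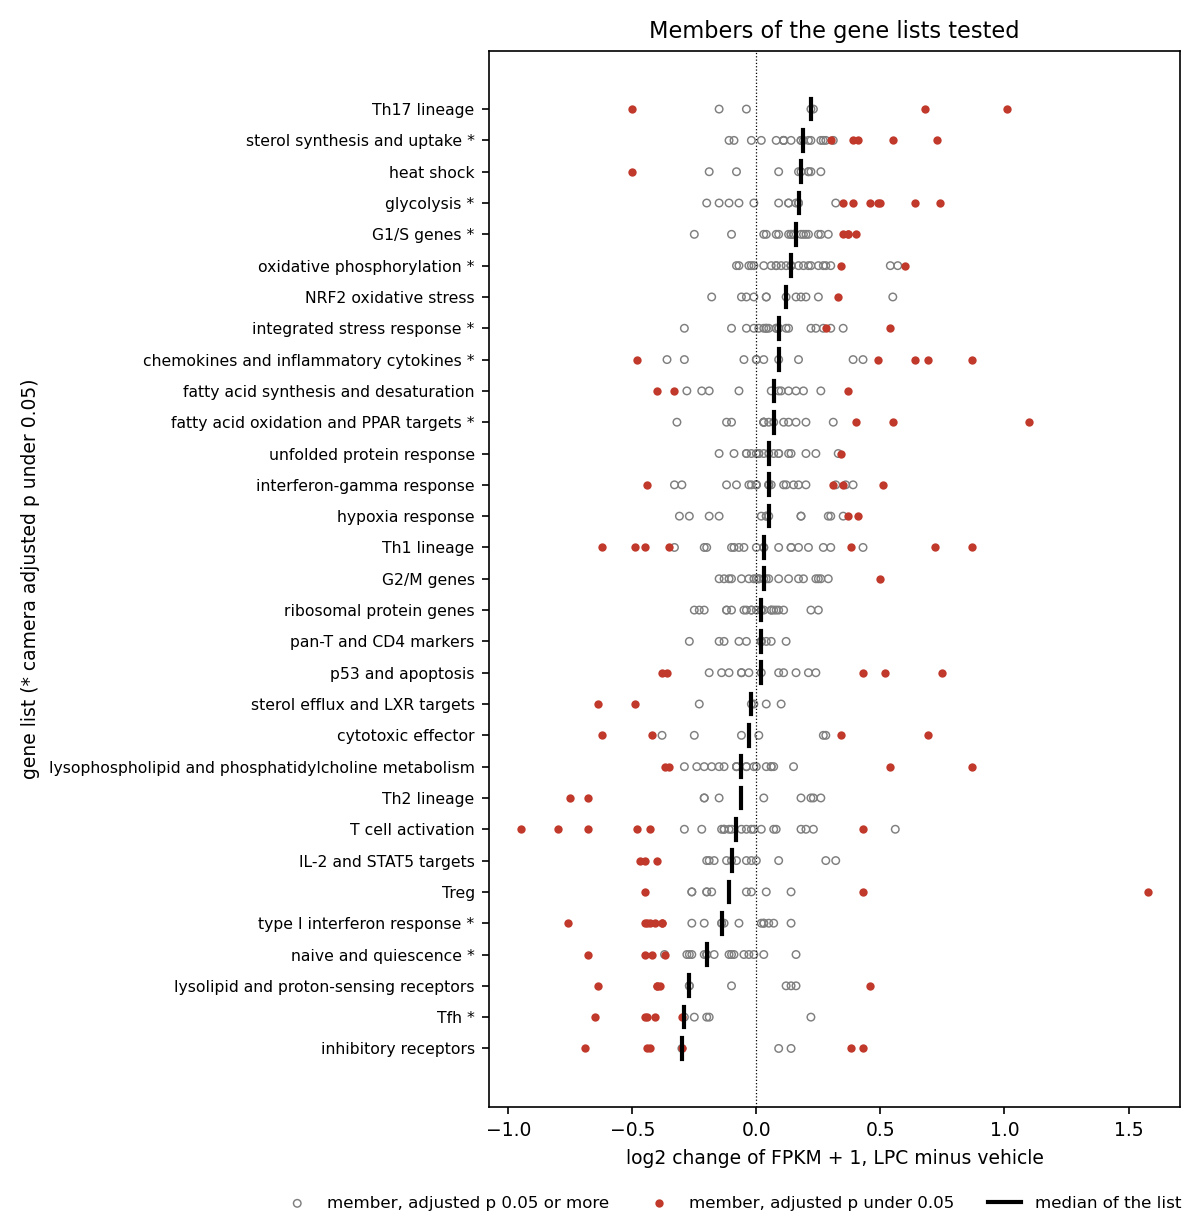
Log2 change of FPKM + 1 (LPC minus vehicle) of each tested member of the 31 lists; filled points passed an adjusted p of 0.05, open points did not, black bars are list medians and an asterisk marks a camera adjusted p under 0.05. The follicular helper median lies at -0.29 and the sterol synthesis median at 0.19; none of the 10 marked shifts held with an estimated correlation.

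Markers of other cell types were mostly under the filter. Cd8a was listed at 0.247 ± 0.0764 and 0.27 ± 0.03 FPKM, and Cd8b1, the 1 tested gene of that list, did not pass (log2 change -0.22). None of the listed granulocyte and mast cell markers passed the filter, while Ly6g, outside that list, rose (limma adjusted p = 4.8e-04). Of B cell markers Cd74 (log2 change -0.39) fell and Ebf1 (0.42) rose. Cd74 did not pass without vehicle replicate 1 (adjusted p = 0.0899), vehicle replicate 2 (0.0716) or LPC replicate 1 (0.0632). Ebf1 did not pass without vehicle replicate 1 (adjusted p = 0.0552), vehicle replicate 2 (0.0564), vehicle replicate 3 (0.119), LPC replicate 1 (0.129) or LPC replicate 2 (0.0812). Of NK cell markers Klrk1 (0.52) rose and Eomes (-0.49) fell. Eomes did not pass without vehicle replicate 2 (adjusted p = 0.055), vehicle replicate 3 (0.0539) or LPC replicate 1 (0.0566). Of 3 tested monocyte and macrophage markers Ctss (-0.40) fell. Ctss did not pass without vehicle replicate 1 (adjusted p = 0.0699), vehicle replicate 3 (0.0503) or LPC replicate 1 (0.0551). Of 4 tested dendritic cell markers H2-Ab1 (0.64) and Batf3 (0.45) rose and Zbtb46 (-0.68) and H2-Eb1 (-0.42) fell. Batf3 did not pass without vehicle replicate 1 (adjusted p = 0.0681), vehicle replicate 2 (0.135), LPC replicate 1 (0.136) or LPC replicate 3 (0.0742). H2-Eb1 did not pass without vehicle replicate 1 (adjusted p = 0.0927), vehicle replicate 3 (0.0797) or LPC replicate 3 (0.06). Sox13 of the gamma-delta and NKT cell markers (0.22) and Car2 of the erythroid and platelet markers (-0.23) did not pass.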

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

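Of the alternatives, removal of the GC and length trends was chosen after seeing the data. Of the 97 named genes that passed, 48 passed in every alternative in which they were tested, among them the metallothionein genes, Il10, Plin2, Fscn1, Gata3, Nr4a1 and Egr3, and no call changed direction. With no filter on low values 44 of the 97 were lost, among them Nr4a3, Stat4, Eomes, Cxcr5, Tcf7, Dapl1, Il7r, Pfkl, Idi1 and Pemt. No list call held in every alternative. The 1392 calls became 464 with no filter on low values, where 16899 genes were tested and 376 calls were shared, and 513 to 2026 when single libraries were left out; the cause was not tested. Lowest were 513 without vehicle replicate 1, 566 without vehicle replicate 2 and 702 without LPC replicate 1. The 20 genes over 2-fold became 57 with a pseudocount of 0.1, which damps low values less, and 18 to 29 without single libraries. The 10 shifted lists became 0 with an estimated correlation and 9 to 12 without single libraries. With fry, which does not compare a list with other genes, 3 lists passed, of which 1 was among the 10. The fatty acid oxidation and PPAR target list held (fry adjusted p = 0.0485). The Th17 and unfolded protein response lists, which camera had not called, also passed (fry adjusted p = 0.0485 each). Trend removal gave 1875 genes, 1237 of them shared, and 13 lists, 9 of them shared. With the replicate number as a block 2841 genes were called, including all 1392 and, beyond them, Il2 (limma adjusted p = 0.00351) and Cd4 (0.0274). Deviations from the group means correlated at 0.02, 0.56 and 0.41 for numbers 1 to 3. Vehicle replicate 2 with LPC replicate 3 gave -0.50, and vehicle replicate 3 with LPC replicate 2 gave -0.45. Vehicle replicate 1 correlated best with LPC replicate 3 (0.06), barely above its own number. The numbers were not taken as pairs in the main test, but these values do not exclude that equal numbers shared a batch. Tests that need read counts were not run.

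Results that turned direction had not passed. After trend removal Ifng stood at 0.00. Mean log2 changes of lists, members minus other genes, stood as follows where the test turned. With quantile normalization they were 0.06 (Treg), -0.02 (cytotoxic effector) and -0.08 (ribosomal protein genes), and with median centring -0.00 (pan-T and CD4 markers). With no filter they were -0.03 (Th2) and 0.04 (Treg), with a mean FPKM of 5 or more -0.07 (cytotoxic effector), and with trend removal 0.06 (Treg) and -0.04 (ribosomal protein genes). fry, whose direction is not relative to other genes, turned for the cytotoxic, fatty acid synthesis and ribosomal lists, which stood at 0.02 each. For lists that turned without a single library, all 6 omissions, turned or not, gave 0.00 to 0.03 (lysophospholipid), -0.03 to 0.03 (pan-T and CD4 markers) and -0.10 to 0.11 (ribosomal protein genes). The cause was not tested.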

Other observations

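Tests of GC and length trends were chosen after the results were seen. The other gene sets, apart from the myeloid genes, Nqo1 and Zbtb16, were written after the patterns were noticed but before their own values were seen. Other genes whose values had been seen were left out of them. Nqo1 (aryl hydrocarbon receptor set) and Zbtb16 (glucocorticoid set) were also in lists of the report, so their values may have been known. Both stayed under the filter and were not tested. Outside the lists of the report, Per1, Spry1 and Fosl2 were lower with LPC. Per1 was listed at 45.4 ± 3.23 FPKM with vehicle and 28.5 ± 6.77 with LPC (SD, 3 libraries each; log2 change -0.68, limma adjusted p = 0.00788). Spry1, a feedback inhibitor of receptor signalling, stood at 46.8 ± 1.63 and 30.6 ± 2.61 FPKM (-0.60, adjusted p = 0.00164), and the AP-1 gene Fosl2 at 94.1 ± 6.95 and 62.6 ± 10.9 FPKM (-0.59, adjusted p = 0.00742).

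The rise of Mt1, Mt2 and Mt3 has several candidate explanations. A glucocorticoid response is argued against by its targets, whose median log2 change over 6 tested genes was -0.30, with none of them risen in the full comparison and 1 risen without LPC replicate 3. These targets ranged from Per1 (-0.68) to Cxcr4 (0.27, limma adjusted p = 0.0934), and Fkbp5 stood at 0.07 (limma adjusted p = 0.623). A trend of single libraries with GC content or length is also argued against, since Mt1 stood at 2.30 after its removal. A metal response stays open: Slc30a1, a zinc exporter gene induced by the same metal sensor, had a log2 change of 0.11 with a 95% interval of -0.11 to 0.33. Slc39a10 (-0.31, interval -0.53 to -0.09, limma adjusted p = 0.0614) and Mtf1 (-0.10, adjusted p = 0.566) of the same set did not pass, and an effect of LPC by another route was not tested.

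Il10, Il22, Ly6g and S100a6 were among 5 genes that rose and were weighed together. Granulocytes and monocytes, which the selection of naive CD4+ cells should remove, are argued against: the highest mean with LPC among Lyz2, S100a9, Ngp, Ltf and Csf1r was 0.22 FPKM. These genes belong to the marker lists of the report, so their low values may have been known when the test was set. Dendritic cells were not part of this test. Activation of the aryl hydrocarbon receptor is argued against only by Tiparp, the 1 target tested (log2 change -0.06, 95% interval -0.29 to 0.17). Cyp1a1 and Ahrr stayed at or under 0.18 FPKM in LPC libraries, but were also far under the filter with vehicle (0.04 and 0.09 FPKM). Nqo1, another target under the filter, was listed at 0.37 ± 0.236 FPKM with vehicle and 0.607 ± 0.129 with LPC. After removal of GC and length trends the median log2 change of the 5 genes was 1.47, and all 5 passed limma. A response of the T cells to LPC may underlie these rises, a hypothesis that no test here addressed.

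Nr4a1, Nr4a3, Egr3, Fos and Jun were lower with LPC, which may reflect a weaker antigen receptor signal at harvest. They were the 5 falls among 24 T cell activation genes, of which 1 rose and 18 did not pass (camera adjusted p = 0.328). Il2, among those that did not pass, had a log2 change of 0.56 (limma adjusted p = 0.0543). Over 23 other early genes the median log2 change was -0.15, 5 fell and none rose (camera p = 0.0088, but p = 0.189 with an estimated correlation). Rises in the early gene list numbered 1 without LPC replicate 3, and falls in the early gene list numbered 2 without vehicle replicate 1 or LPC replicate 1 and 3 without vehicle replicate 2. After removal of GC and length trends the median of the 5 genes was -0.70, against -0.68 before, which argues against such a trend. The time of harvest and the density of the cultures were not tested.

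The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. For each of these 3 results, 1 split, the real one, gave a value as large: 1392 changed genes, with 0 as the highest of the other splits, 20 genes over 2-fold, with 0, and 10 shifted lists, with 9. Every other split, each mixing LPC and vehicle libraries, shifted 2 to 9 lists by camera with the preset correlation. The number of shifted lists therefore set the real split apart far less than the gene counts did.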
